A study of Trifolium pratense with 9 samples.

How the data were processed

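Poly(A)-selected, strand-specific RNA libraries from roots of red clover (Trifolium pratense) were analysed. Per the labels' protocols, seedlings raised from bleach-treated seed in sterile semi-solid medium received an agar plug carrying fungal hyphae at the root, or a sterile plug as the mock treatment, and roots were frozen at harvest. The labels give 3 groups of 3 libraries: mock-inoculated roots harvested at 7 days post inoculation (dpi), roots inoculated with the fungus Phoma medicaginis harvested at 3 dpi, and Phoma-inoculated roots harvested at 7 dpi. No mock group at 3 dpi was analysed here, so comparisons that involve the 3 dpi group combine infection with 4 days of plant age. The series title also names Fusarium, for which no library was analysed here. Nothing in the labels says that replicates came from separate plants or boxes, so p-values measure only the spread between these samples, which may be technical.

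The deposited values were raw read counts per gene, 1 table per library, with no normalization. FastQC, Trimmomatic and STAR version 2.7.11 were used upstream, per the submitters' processing notes; the settings, genome build and annotation are not given in the sources used here. The tables have the layout of STAR gene counts, and their names mark them as the reverse-strand column. Each table holds 41335 gene IDs and 4 summary lines for unmapped reads, reads mapping to several places, reads outside genes and reads that fit more than 1 gene. The summary lines were kept out of library sizes and tests, and their shares of all reads are reported as values. Reads that map to several places are not counted for any gene, so counts of near-identical copies, such as rRNA genes, are uncertain.

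Gene symbols and gene types came from a RefSeq gene table of assembly ARS_RC_1.1, in which 40594 of the 41335 IDs were found. The 741 IDs without a match were numbered tRNA copies. The table gives no product names: 40384 IDs carry only a LOC symbol, and these held at least 99.4% of the gene reads in every library. Therefore none of the 50 gene lists fixed as product-name patterns before the data were examined matched at least 3 genes, and the planned test of those lists could not be computed. In their place, 17 groups of genes, defined by organelle gene symbols or by gene type, were tested; they were chosen after the data were examined. No coordinates are given, because the build used for counting is not given in the sources used here. The table served for names and for which genes neighbour each other.

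All comparisons used R 4.3.3. The main test was edgeR 4.0.16's quasi-likelihood F test on the deposited counts of all 9 libraries, with group as the only factor, TMM normalization, edgeR's default expression filter (26228 genes tested) and Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. These choices, the 3 comparisons between groups and the rule for named genes were fixed before the data were examined. A comparison of all 6 Phoma libraries with the 3 mock libraries, fitted with 2 groups, was added after the data were examined. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Normalised counts (CPM) were computed from the deposited counts with TMM-scaled library sizes. The rule for named genes took, per comparison and direction, the called genes with the largest log2 fold changes among those with a mean log2 CPM of at least 1 and no overlap between the groups' libraries: 8 per direction for ranges, and 2 per direction by name, because product names were lacking. Genes named outside this rule were chosen after their values were seen, and are introduced as such. Gene groups with at least 3 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 17 groups, beside camera with an estimated correlation and fry. Shares of reads were compared with exact two-sided permutation tests, for which the smallest p is 0.1 with 3 against 3 libraries and 0.0238 with 6 against 3.

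Libraries held 65078668 to 88775702 reads, of which 40.7 to 67.0 M were counted in genes. A gene with 0 counts in a library lies below 3 counts, which is 0.0447 to 0.0737 CPM before TMM scaling, depending on the library. Intervals and this floor cover counting error only. The common dispersion was 0.412, a biological coefficient of variation of 0.642. The tests were checked on simulated data drawn from the real means and library sizes with 200 changed genes. For Phoma 7 dpi against mock, over 25814 simulated genes, edgeR recovered 0% of the 2-fold, 16.4% of the 4-fold and 53.0% of the 8-fold changes, with 4 false among 50 calls; DESeq2 made 126 false among 224 calls, and limma-voom 2 among 51. For Phoma 3 dpi against mock edgeR recovered 59.1% of the 8-fold changes, and for Phoma 7 dpi against Phoma 3 dpi 47.0%. Recovery and the share of false calls depend on how many genes change, so they need not hold for the real comparisons.

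Alternatives were DESeq2's size factors, upper quartile normalization, no expression filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a replicate block, and each library left out in turn; shares of reads were also computed over mapped reads. Chance overlap from the shared mock libraries was estimated from 40 simulations of unchanged groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.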

Results

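Root transcriptomes were profiled by RNA sequencing in 9 libraries of red clover: 3 from mock-inoculated roots at 7 dpi, 3 from roots inoculated with Phoma medicaginis at 3 dpi and 3 from Phoma-inoculated roots at 7 dpi. Reads counted in genes came to 67.0, 54.3 and 58.3 M in mock replicates 1, 2 and 3, to 51.6, 50.1 and 40.7 M in the Phoma 3 dpi replicates, and to 49.6, 64.7 and 54.2 M in the Phoma 7 dpi replicates. Between 28492 and 29258 genes had at least 1 read in a library, and the most abundant gene took at most 2.12% of the gene reads of any library.

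The share of reads that did not map to the clover genome was 3.88% ± 0.0748 of all reads in mock roots, 29.1% ± 15.9 in Phoma roots at 3 dpi and 16.7% ± 10.5 at 7 dpi (mean ± SD, n = 3 each). Every Phoma library lay above every mock library. The Phoma libraries themselves ranged from 4.79% in 7 dpi replicate 2 to 46.8% in 3 dpi replicate 3. Each Phoma group against mock gave an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Over all 6 Phoma libraries (22.9% ± 13.8) the exact permutation p was 0.0238, the smallest possible there, or 0.32 after Benjamini-Hochberg adjustment over 16 comparisons of read shares. Most of the 16 tests cannot give a p below 0.1, so no adjusted value in this family could fall below 0.05. The adjusted value therefore does not speak against a difference. The 2 Phoma groups differed by less than their spread (exact permutation p = 0.4). As a share of mapped reads, reads outside annotated genes were 3.61% ± 0.119 in mock (n = 3) and 4.09% ± 0.213 in Phoma libraries (n = 6). The exact permutation p was 0.0238, or 0.127 after adjustment over the 16 comparisons, where the same limit holds. As a share of all reads they were 0.301 percentage points lower in Phoma libraries (exact permutation p = 0.476).

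**Figure D1:**
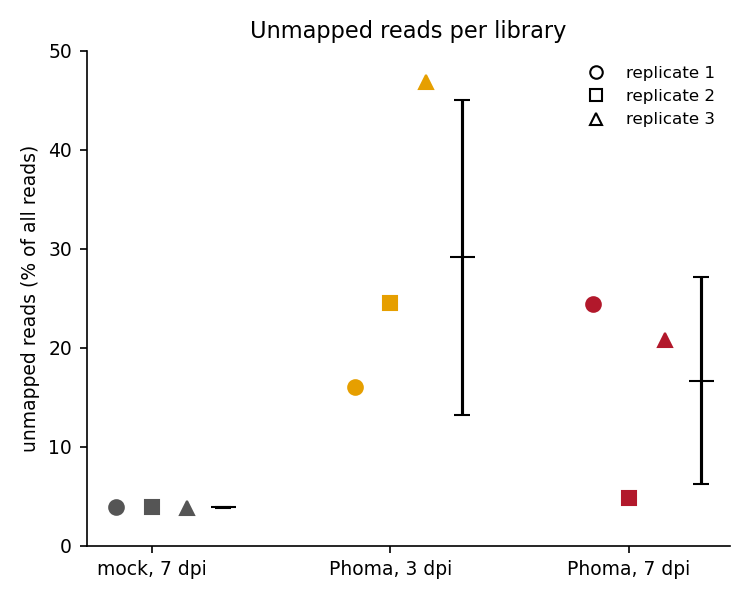
Share of all reads that did not map, in percent, for each library (points) by group, with a bar for the group mean and SD. Mock libraries sit between 3.79% and 3.93%, and Phoma libraries between 4.79% and 46.8%.

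Mock libraries resembled each other most on average, with correlations of log2 CPM between 0.902 and 0.911. Phoma 7 dpi replicates 1 and 3 correlated at 0.907, within that range. The mean correlation of log2 CPM across genes was 0.905 among mock libraries, 0.871 among Phoma 3 dpi libraries and 0.864 among Phoma 7 dpi libraries, against 0.858 between mock and Phoma 3 dpi and 0.824 between mock and Phoma 7 dpi; genes are not independent replicates. The first principal component (34.1% of variance) placed the mock libraries between -124 and -93.9 and Phoma 7 dpi replicates 1 and 3 at 143 and 154. Phoma 7 dpi replicate 2 lay at -17.6 and Phoma 3 dpi replicate 1 at -78.0, on the mock side of their groups.

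**Figure D2:**
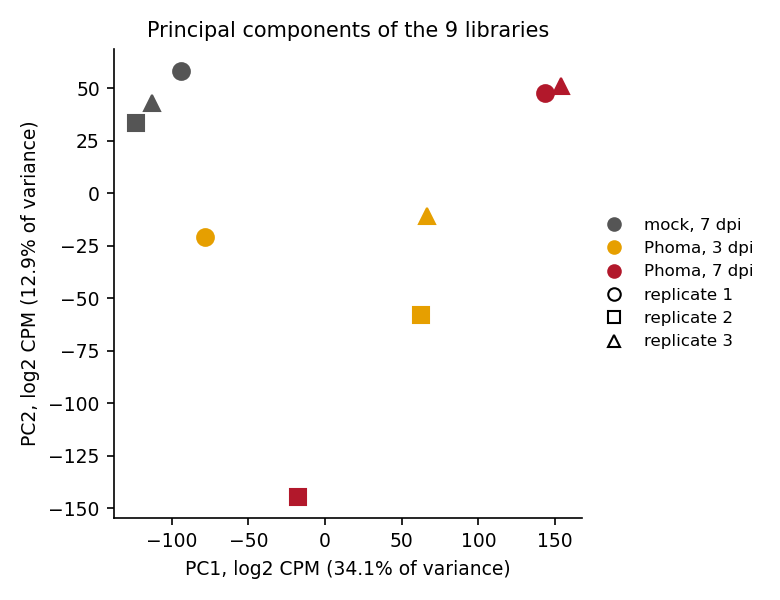
First against second principal component of log2 CPM over all tested genes, 1 point per library, coloured by group. The 3 mock libraries lie together on the left, and Phoma 7 dpi replicate 2 lies apart from the other 2 libraries of its group on both axes.

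Phoma-inoculated roots at 7 dpi were compared with mock roots of the same age to ask which root genes respond to the fungus. LOC123918761, a protein-coding gene, rose from 7.32 ± 3.16 CPM in mock to 3286 ± 2772 CPM (mean ± SD, n = 3 each), a log2 fold change of 8.81 (SE 1.76, edgeR adjusted p = 0.0466). Its Phoma 7 dpi libraries read 5153, 100.2 and 4603 CPM, lowest in replicate 2, which had few unmapped reads. Whether reads of the fungus were counted on this gene was not tested. LOC123914561 was close to undetected in mock, with 1 read in 3 libraries, and had 14, 859 and 322 reads in the Phoma 7 dpi libraries, a ratio of normalised counts of 1561 (95% counting interval 280 to 61714; edgeR adjusted p = 0.0382). In the other direction, LOC123899970 fell by 7.89 on the log2 scale (SE 1.10, edgeR adjusted p = 0.0348), from 31.0 ± 4.32 to 0.125 ± 0.127 CPM. LOC123906576 fell by 8.81 (SE 1.54, edgeR adjusted p = 0.0368), from 24.9 ± 13.9 to 0.0546 ± 0.0455 CPM, or 2, 1 and 5 reads in the Phoma libraries.

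In all, 630 of 26228 genes passed edgeR's threshold at 7 dpi, 347 higher and 283 lower in Phoma roots, and 611 of them changed by at least 2-fold (340 higher, 271 lower). The 8 leading risers spanned fitted log2 fold changes of 7.22 to 9.96, where the upper end belongs to LOC123914561 and depends on the fit's prior count, and the 8 leading fallers -8.81 to -5.40. Among protein-coding genes 331 rose and 282 fell. The share of rising calls was 55.1% with TMM, 59.7% with DESeq2's size factors and 46.4% with upper quartile normalization, so the majority direction is not fixed by these data. At an unadjusted p below 0.05 there were 6723 genes (25.6%). The Phoma 7 dpi and mock libraries did not overlap in 9168 genes (35.0%, where chance gives 10%), including all 630 called genes.

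Long non-coding RNA (lncRNA) genes, which make transcripts without a recognised protein product, were mostly higher in Phoma roots at 7 dpi. Of 1718 tested, 1172 had a positive log2 fold change (median 0.59), 16 rose and 1 fell, and 7 were called when adjusted over the group alone. As examples chosen after their values were seen, LOC123921633 rose from 266 ± 20.8 to 1608 ± 472 CPM (log2 fold change 2.60, SE 0.32, edgeR adjusted p = 0.0331, n = 3 each) and LOC123910317 from 972 ± 130 to 2850 ± 322 CPM (1.55, SE 0.30, edgeR adjusted p = 0.0445). Genes for small nuclear RNAs (snRNA), the RNA parts of the splicing machinery, were higher in 33 of 37 (median 1.06), and nuclear ribosomal RNA (rRNA) genes in 150 of 168 (median 0.71). The nuclear rRNA share of gene reads was 0.0512% and 0.0467% in Phoma 7 dpi replicates 1 and 3, but 0.01265% in replicate 2, below every mock library (0.0189% to 0.0248%). The preset-correlation camera test in limma gave adjusted p = 4.77e-04 for lncRNA, 4.77e-04 for snRNA and 4.39e-04 for rRNA genes. With an estimated correlation none of the 3 groups passed: the adjusted p was 0.17 for lncRNA, 0.53 for snRNA and 0.949 for rRNA genes. The estimates were 0.0114, 0.0842 and 0.446 in that order, so the one for lncRNA genes hardly differed from the preset 0.01. Without Phoma 7 dpi replicate 1 the rRNA group had a preset camera adjusted p of 0.0624. No rRNA or snRNA gene passed on its own. The libraries were poly(A)-selected, and how well they capture such RNAs was not tested, so these counts may not measure abundance. Reads outside annotated genes, as a share of mapped reads, were also 0.601 percentage points higher in Phoma 7 dpi than in mock libraries (exact permutation p = 0.1, the smallest possible).

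The count of 630 changed strongly when single libraries were left out, from either group. With all 9 libraries the lowest adjusted p in edgeR was 0.0169, so every call lay close to the threshold of 0.05. The Phoma 3 dpi libraries enter this comparison only through the shared fit. Without mock replicate 1, 2 or 3 edgeR called 0, 2 and 2 genes; without Phoma 7 dpi replicate 1 or 3, 1 and 0; without Phoma 3 dpi replicate 3, 8; without Phoma 3 dpi replicate 1, 1391; and without Phoma 7 dpi replicate 2, 3110. The fitted log2 fold changes of the named genes moved too. LOC123914561 went from 8.92 without Phoma 7 dpi replicate 2 to 11.6 without mock replicate 3, LOC123918761 from 8.36 without Phoma 7 dpi replicate 1 to 9.38 without replicate 2, LOC123899970 from -9.16 without Phoma 7 dpi replicate 2 to -7.44 without replicate 1, and LOC123906576 from -9.67 without Phoma 7 dpi replicate 3 to -8.27 without mock replicate 3.

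**Figure D3:**
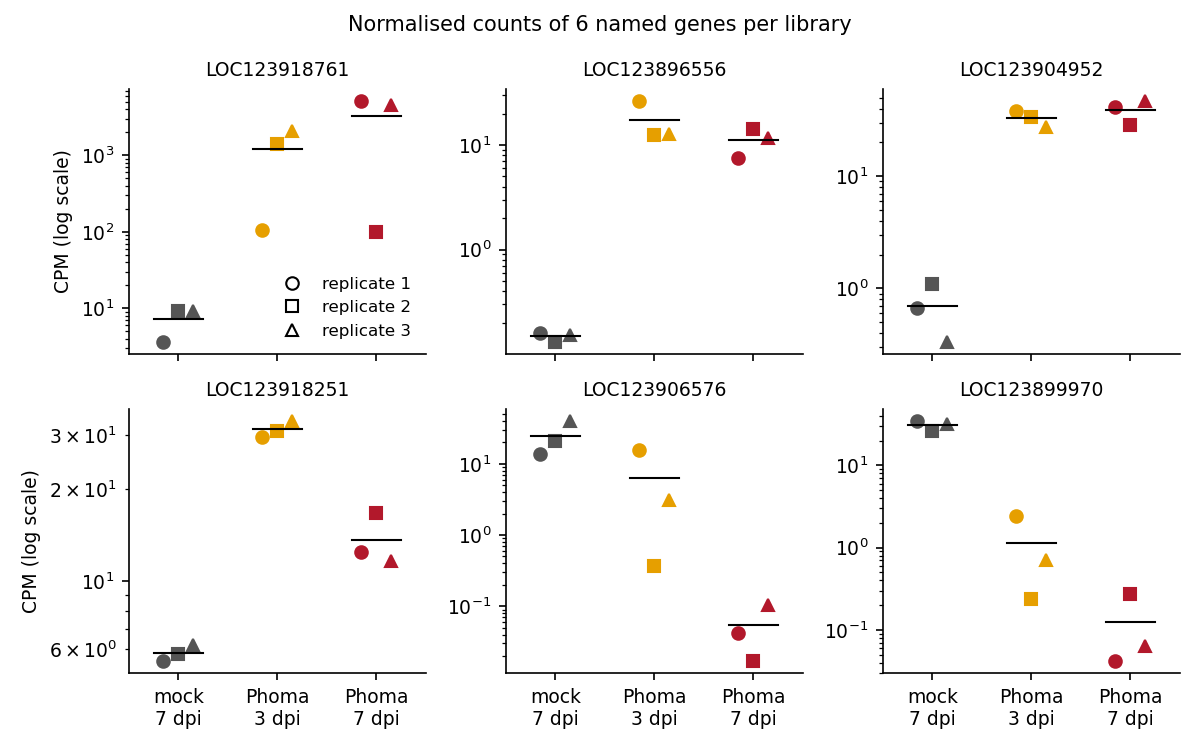
Normalised counts of 6 named genes in CPM on a log axis, 1 point per library by group, with a line at the group mean. LOC123906576 and LOC123899970 lie below every mock library in the 3 Phoma 7 dpi libraries, and LOC123896556 and LOC123904952 lie above every mock library in all 6 Phoma libraries.

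**Figure D4:**
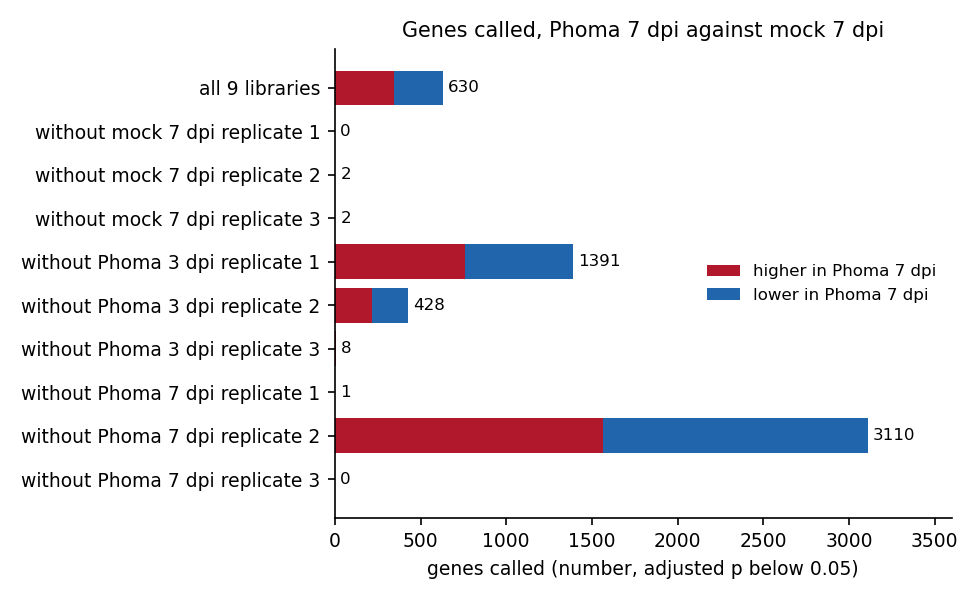
Number of genes called by edgeR for Phoma 7 dpi against mock from all 9 libraries and with each library left out, as bars split into genes higher and lower in Phoma 7 dpi. The count runs from 0 to 3110 around 630.

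Phoma roots at 3 dpi were compared with the 7 dpi mock roots to see which genes differ early after inoculation, with plant age differing by 4 days. Only 3 genes passed edgeR's threshold, all higher in Phoma roots, and all 3 are given here. LOC123896556 rose from 0.148 ± 0.0139 to 17.3 ± 7.87 CPM, 115-fold (log2 fold change 6.85, SE 0.49, edgeR adjusted p = 0.0102, n = 3 each). LOC123904952 rose from 0.704 ± 0.385 to 33.3 ± 5.57 CPM, 47.3-fold (5.56, SE 0.48, edgeR adjusted p = 0.0213). LOC123918251, the third by size of change, rose 5.40-fold, from 5.81 ± 0.350 to 31.3 ± 1.92 CPM (2.43, SE 0.22, edgeR adjusted p = 0.0215).

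By group, snRNA genes were higher at 3 dpi than in mock in 35 of 37 (median log2 fold change 1.12) and lncRNA genes in 1153 of 1718 (median 0.46), with no single member called. The preset camera test in limma gave adjusted p = 1.48e-05 and 0.00467, and with an estimated correlation the adjusted p was 0.274 and 0.256. At an unadjusted p below 0.05 there were 4096 genes (15.6%), and libraries of the 2 groups did not overlap in 6871 genes (26.2%, where chance gives 10%). DESeq2 called 2078 genes and limma-voom 3. Leaving out 1 library changed the count of 3 to 132 without Phoma 3 dpi replicate 1, to 51 without Phoma 7 dpi replicate 2, to 0 without mock replicate 1, and to 1 without Phoma 3 dpi replicate 2 or Phoma 7 dpi replicate 1 or 3.

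The same 3 genes were called at 7 dpi. There LOC123896556 read 11.1 ± 3.35 CPM (log2 fold change against mock 6.21, SE 0.48, edgeR adjusted p = 0.0169), LOC123904952 38.8 ± 9.47 CPM (5.78, SE 0.48, adjusted p = 0.0169) and LOC123918251 13.6 ± 2.67 CPM (1.23, SE 0.21, adjusted p = 0.036). Both comparisons share the mock libraries: log2 fold changes correlated across genes at 0.694, against 0.497 (SD 0.011) in simulated unchanged groups, and their covariance was 1.26 against 0.385, a difference of 0.879. Over all genes tested, 77.9% had the same sign in both comparisons, against 66.7% in the simulated groups. Independent lists would share 0.0397 rising genes. Simulated unchanged groups shared 0, but few calls are made without an effect, so that 0 does not measure what the mock libraries add to the overlap. The simulated comparisons already shared their mock libraries, with the same spread in every group. The real mock libraries were more alike (mean correlation 0.905) than the Phoma 3 dpi (0.871) and 7 dpi libraries (0.864). The 3 mock libraries were not divided between the comparisons, so whether any of the excess in correlation and same-sign share comes from them was not tested.

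Phoma roots at 7 dpi and at 3 dpi were compared directly, which also tests whether their differences from mock differ. With no gene called, genes named above serve as examples, chosen after their values were seen. LOC123918251 was at 13.6 CPM at 7 dpi and 31.3 CPM at 3 dpi, a log2 fold change of -1.20 (SE 0.21, edgeR adjusted p = 0.439, n = 3 each). LOC123899970 had a log2 fold change of -3.13 (SE 0.92, edgeR adjusted p = 0.684). Nuclear rRNA genes were higher at 7 dpi in 140 of 168 (median 0.49). The preset camera test in limma gave an adjusted p of 7.12e-04 for rRNA genes and an estimated correlation an adjusted p of 0.984; the preset value was 0.998 without Phoma 7 dpi replicate 1 and 0.312 without replicate 3. EdgeR called 0 genes between the 2 time points (lowest adjusted p = 0.409), with 1901 (7.25%) at an unadjusted p below 0.05, 306 called by DESeq2 and 0 by limma-voom. Without Phoma 7 dpi replicate 2 edgeR called 3. The libraries of the 2 groups did not overlap in 2573 genes (9.81%, where chance gives 10%).

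All 6 Phoma libraries were set against the 3 mock libraries, a comparison chosen after the data were examined, to ask which genes differ from mock over the pooled harvests. LOC123883579 rose from 4.46 ± 4.84 CPM in mock to 2168 ± 2040 at 3 dpi and 3701 ± 3021 at 7 dpi (log2 fold change 9.36, SE 1.92, edgeR adjusted p = 0.0457). LOC123909202 rose from 0.148 ± 0.101 CPM to 178 ± 154 and 296 ± 276 (10.64, SE 2.19, edgeR adjusted p = 0.0457). Both were far lower in Phoma 3 dpi replicate 1 and Phoma 7 dpi replicate 2 than in the other 4 Phoma libraries. LOC123883579 read 83.0 and 290 CPM in those 2 libraries, against 2263 to 6038 CPM in the other 4. LOC123909202 read 3.15 and 4.61 CPM, against 235 to 552 CPM. Whether reads of the fungus were counted on these 2 genes was not tested. LOC123898831 fell from 17.4 ± 7.65 CPM to 0.489 ± 0.202 and 0.134 ± 0.0717 (-5.79, SE 0.68, edgeR adjusted p = 0.0217). LOC123889108 fell by 7.53 on the log2 scale (SE 1.57, edgeR adjusted p = 0.0474), from 23, 1448 and 134 reads in mock to at most 12 reads in any Phoma library. Taken by harvest, LOC123883579, LOC123909202 and LOC123889108 passed edgeR's threshold neither at 7 dpi (adjusted p = 0.0506, 0.0506 and 0.0693) nor at 3 dpi (0.127, 0.127 and 0.189), and LOC123898831 passed it at 7 dpi but not at 3 dpi. In all, 580 genes were called, 311 higher and 269 lower, and 492 changed by at least 2-fold. The share of rising calls was 53.6% with TMM, 59.2% with DESeq2's size factors and 45.9% with upper quartile normalization. The majority direction is therefore not fixed here either. All 12 lncRNA genes called were higher. Libraries did not overlap in 4182 genes (15.9%, where chance gives 2.38%).

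Single libraries moved this count as well. Without mock replicate 1, 2 or 3 edgeR called 0, 2 and 4 genes, without Phoma 3 dpi replicate 1, 2 or 3 it called 3036, 3 and 131, and without Phoma 7 dpi replicate 1 or 3 it called 51 and 8.

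Among nuclear rRNA genes, LOC123882617 was singled out after its values were seen. It read 2.52 ± 0.738 CPM in mock, 52.5 ± 42.7 at 3 dpi and 45.6 ± 38.3 at 7 dpi, and did not pass edgeR's threshold at 3 dpi (adjusted p = 0.174) or 7 dpi (adjusted p = 0.0912). Its count was 85 in Phoma 7 dpi replicate 2, the Phoma library with the fewest unmapped reads, and 1002 to 3805 in the other 5 Phoma libraries.

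**Figure D5:**
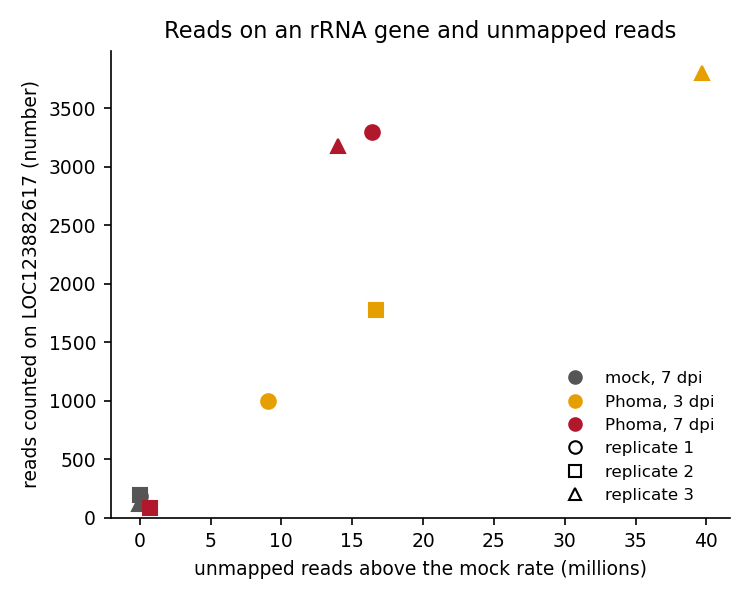
Reads counted on the rRNA gene LOC123882617 against unmapped reads above the mock rate (in M reads), 1 point per library, coloured by group. Phoma 7 dpi replicate 2, with 85 reads, lies beside the mock libraries, which have 118 to 199.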

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

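The tests in this part were chosen after the results were seen, and the criteria of the rRNA tests were revised after their outcomes were seen: earlier criteria accepted a fungal source for LOC123882617 and argued against it for mitochondrial rrn18 and rrn26. The rRNA gene LOC123882617 stood out because rRNA is outside what poly(A) libraries are made to measure, yet it averaged 52.5 CPM at 3 dpi and 45.6 CPM at 7 dpi against 2.52 CPM in mock, and a candidate explanation is that reads of the fungus aligned to this conserved gene. Per M unmapped reads above the mock level, its excess count was 93.0 to 98.3 in the 3 Phoma 3 dpi libraries and 192 and 216 in Phoma 7 dpi replicates 1 and 3, so the highest rate was 2.32 times the lowest. In Phoma 7 dpi replicate 2 the excess was -98.2 reads, below the mock libraries (-47.0 to 45.3), where a constant fungal rate would give a positive one. This is 1 library with only 0.755 M unmapped reads above the mock level, so this source stays open. A change in plant rRNA was not tested. For mitochondrial rrn18 and rrn26 the highest 7 dpi rate was 8.84 and 6.10 times the highest 3 dpi rate, which a constant fungal rate would not give. The excess was negative for rrn18 in Phoma 3 dpi replicate 1 (-858 reads) and Phoma 7 dpi replicate 2 (-4959). For rrn26 it was negative in Phoma 7 dpi replicate 2 (-16615). That replicate had only 0.755 M unmapped reads above the mock level, so its deficits cannot decide on fungal reads in the other libraries. Mock libraries vary as well (-3155 to 2028 reads for rrn18 and -7428 to 5590 for rrn26). A rate that changes by day was not tested, so fungal and plant origins cannot be told apart.

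Phoma 7 dpi replicate 2 lay nearer to mock than the other 2 libraries of its group. Of the 3110 genes called without it, 3083 also passed the expression filter with all libraries, and over these its median position was 0.401, where 0 is the mock mean and 1 the mean of the other 2 (quartiles 0.127 to 0.666). Mock libraries held out in turn lay at 0.0771, 0.0226 and 0.102 over other sets of genes, selected without each of them (367, 500 and 299 genes), and its CPM of LOC123904952 was 28.3 against at most 1.10 in mock, which argues against a mislabelled mock library. Lower depth is argued against too, since it held 10.5 M more gene reads than the deeper of the other 2. Over the same 3083 genes Phoma 3 dpi replicates 1, 2 and 3 lay at 0.308, 0.629 and 0.586, on both sides of 0.401. A swap with a 3 dpi library was not examined. On the second principal component Phoma 7 dpi replicate 2 lay at -144.5, against 33.7 to 58.5 in mock and 47.7 and 51.2 in replicates 1 and 3. It therefore did not simply lie between mock and those 2 libraries. A weaker or later infection of those roots may account for part of this and was not tested, its unmapped share being 4.79%.

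Genes called higher in Phoma roots at 7 dpi could in part hold reads of the fungus aligned to plant genes. In replicate 2 the excess of unmapped reads per gene read was 3.96% of that in replicates 1 and 3, and fungal reads alone would lower the genes' excess to that level. Over the 1535 of those 3083 genes that were called higher, the median excess in replicate 2 was 11.1% (quartiles -2.47% to 42.8%), and 613 genes lay at or below 3.96%. Plant genes that respond less in replicate 2 would give such low values as well. The fungal genome was not used here, and neither counting error around that level nor a mixture of sources was tested, so for the genes called higher the sources cannot be told apart.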

How the results depend on the processing

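The comparison of all Phoma libraries with mock and the 17 gene groups were chosen after seeing the data, as were their alternatives; all others were planned. The 7 genes named for the planned comparisons kept their direction in all 17 alternatives each, but kept their call in only 7 to 12 of them. The lncRNA group at 7 dpi kept its camera call in 15 of 15 alternatives with the preset correlation. It lost the call in camera with an estimated correlation (adjusted p = 0.17). That estimate was 0.0114 against the preset 0.01, so a high correlation among lncRNA genes does not account for the loss. With the preset correlation each other group called at 7 or 3 dpi kept its call in 14 of 15: with a mean of at least 1 CPM the snRNA group lost it at 7 dpi (adjusted p = 0.413) and at 3 dpi (0.123), with no expression filter the lncRNA group at 3 dpi (0.0611), and without Phoma 7 dpi replicate 1 the rRNA group at 7 dpi (0.0624). Other normalizations left every count of calls within 1.5 times. With no expression filter, edgeR called 390 genes at 7 dpi (389 at least 2-fold) and 327 (299) for all Phoma libraries, and 1 gene group at 3 dpi. With a mean of at least 1 CPM, 1 gene group was called at 3 dpi. DESeq2 called 5016 genes (3917 at least 2-fold) at 7 dpi, 2078 (1519) at 3 dpi, 306 (277) between the time points and 4156 (2815) for all Phoma libraries, with 1591 shared between 3 and 7 dpi; for 7 dpi it called up to 680 in other splits of the same libraries, and 126 of its 224 calls on simulated data were false. Limma-voom called 1411 (1122) for all Phoma libraries. Camera with an estimated correlation called 0 groups at 7 dpi, 0 at 3 dpi and 0 between the time points, and fry 2 at 7 dpi, 2 at 3 dpi (the snRNA and lncRNA groups in both) and 0 between the time points. The cause was not tested.

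With the replicate block edgeR called 0 genes at 7 dpi (0 at least 2-fold), 0 at 3 dpi (0), 16 for all Phoma libraries (16), and 0 shared between 3 and 7 dpi; it changed no call of a gene group. A check gave no sign that the replicate numbers pair the samples. Of 9 pairs with the same number, 1 had deviations correlated over 0.1 (range -0.16 to 0.13), and 3 libraries correlated best with their own number. The wide differences among Phoma libraries of a group could hide a pairing, so the check cannot exclude one.

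Leaving out each library in turn gave 0 to 3110 genes at 7 dpi (0 to 2892 at least 2-fold; the count was highest without Phoma 7 dpi replicate 2), 0 to 132 at 3 dpi (0 to 132), 0 to 3 between the time points (0 to 3), 0 to 3036 for all Phoma libraries (0 to 2229) and 0 to 120 shared between 3 and 7 dpi. Gene groups called ranged from 2 to 4 at 7 dpi, 2 to 4 at 3 dpi and 0 to 3 between the time points. The difference in unmapped reads from mock stayed positive, 8.91 to 18.7 points at 7 dpi, 16.4 to 31.8 at 3 dpi and 14.2 to 22.6 for all Phoma libraries. The difference in reads outside genes ranged from -0.247 to 0.22 points at 7 dpi, turning negative without mock replicate 1 (-0.0236) or Phoma 7 dpi replicate 2 (-0.247). That in ambiguous reads ranged from -0.0615 to 0.00175 at 3 dpi, positive without Phoma 3 dpi replicate 3 (0.00175), and from -0.00992 to 0.0275 for all Phoma libraries, negative without mock replicate 3 (-0.00992), Phoma 3 dpi replicate 2 (-7.1e-04) or Phoma 7 dpi replicate 2 (-0.00237). The difference in multimapping reads for all Phoma libraries ranged from -1.62 to -0.793. Over mapped reads instead of all reads, differences changed sign from those over all reads: multimapping reads 0.596 points at 7 dpi, 0.521 at 3 dpi and 0.559 for all Phoma libraries, reads outside genes 0.358 at 3 dpi and 0.479 for all, and ambiguous reads 0.133 at 3 dpi and -0.0141 between the time points. Unmapped reads enlarge the first denominator, which accounts for these changes. The difference in ambiguous reads for all Phoma libraries kept its sign and grew to 0.126. The planned test of lists fixed by product name, with its alternatives, was not run, because the gene table gives no product names. At this depth and spread, edgeR found 0% of simulated 2-fold changes at 7 dpi, so many changes of that size would be missed, although some called genes changed by less.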

Other observations

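The tests in this part were chosen after the results were seen. Plastid and mitochondrial genes were not called singly at 7 dpi (0 of 78 and 0 of 34 by edgeR). How well poly(A)-selected libraries capture their transcripts was not tested. The 10 plastid NDH genes, which encode a complex of electron transport around photosystem I, all had negative log2 fold changes, with a median of -0.77 at 7 dpi (preset camera adjusted p = 0.242, limma) and -0.61 at 3 dpi (adjusted p = 0.0872). Photosystem genes had a positive value in 8 of 20 at 7 dpi (median -0.08). Mitochondrial complex I genes were higher in 8 of 9 (median 0.35) and the 4 genes for cytochrome c maturation in 4 of 4 (median 0.67), with camera adjusted p = 0.771 for both. In Phoma 7 dpi replicate 2 all 9 complex I genes lay below every mock library (nad1 at 0.61 CPM against 1.30 to 2.21 in mock), so replicates 1 and 3 carry these higher values; the mitochondrial share of gene reads was 0.029% in replicate 2, 0.0465% to 0.0792% in mock, and 0.311% and 0.237% in replicates 1 and 3. The plastid share of gene reads was 0.286% ± 0.0234 in mock (n = 3) and 0.228% ± 0.0452 in Phoma libraries (n = 6; exact permutation p = 0.143, 0.238 after adjustment over 5 shares).

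Small nucleolar RNA (snoRNA) genes, which guide the modification of rRNA, had fold changes in both directions, and no single member passed edgeR's threshold (lowest adjusted p = 0.0741 at 7 dpi and 0.114 at 3 dpi). At 7 dpi 40 of 70 were higher than in mock (camera adjusted p = 0.771, limma), and at 3 dpi 49 of 70 (median 0.41, adjusted p = 0.0526); with an estimated correlation the adjusted p was 0.949 and 0.819. Fry's mixed test, which asks whether members change in either direction, gave adjusted p = 3.69e-04 at 7 dpi and 7.07e-05 at 3 dpi. It does not ask whether they change more than other genes. Of all genes tested, 25.6% at 7 dpi and 15.6% at 3 dpi had an unadjusted edgeR p below 0.05. The lncRNA and snRNA groups passed the mixed test as well, so it shows nothing particular to snoRNA genes. The capture of snoRNA by poly(A) selection was not tested either.

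The lncRNA share of gene reads was 0.875% ± 0.0426 in mock (n = 3) and 1.46% ± 0.183 in Phoma libraries (n = 6), higher in 6 of 6 (exact permutation p = 0.0238, the smallest possible, and 0.0595 after adjustment over 5 shares). Part of this rise rests on 2 abundant genes. LOC123910317 averaged 972 CPM in mock, 2067 at 3 dpi and 2850 at 7 dpi, and LOC123921633 266, 1212 and 1608 CPM. Called lncRNA genes at 7 dpi were split 16 to 1 between higher and lower, and coding genes 331 to 282 (Fisher's exact p = 7.49e-04; genes are not independent replicates). A candidate technical explanation is that weakly expressed genes of any type rise with a background of reads. Coding genes matched on mean expression had a median log2 fold change of -0.25 over 1000 draws (highest draw -0.16), against 0.59 for lncRNA genes, which argues against it. A rise of lncRNA transcription may be involved, as a hypothesis only, since other sources of reads on these genes were not tested.

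The share of unmapped reads, taken as a stand-in for the amount of fungus in a root, was set against expression within each harvest day. Genes at an unadjusted p below 0.05 numbered 4647, and 1 of the 36 assignments of the shares within the Phoma groups, the real one, gave as many (highest other 4623). By edgeR's adjusted threshold 129 genes were called, 58 with positive and 71 with negative slopes, and 2 of the 36 assignments gave as many (highest other 170). On both measures the highest other assignment only exchanged Phoma 7 dpi replicates 1 and 3. Their unmapped shares were close (24.5% and 20.8%, against 4.79% in replicate 2), so it nearly repeats the real one. The 7 dpi part of the pattern thus rests mainly on replicate 2. A link between fungal load and expression within a day therefore stays open.

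Called genes at 7 dpi lay next to each other more often than random positions would give: 18 adjacent pairs were called in the same direction, against a mean of 8.54 and a highest value of 23 over 10000 draws matched on expression (permutation p = 0.0025). Neighbours were taken from assembly ARS_RC_1.1. The longest run of rising genes had 3 members, named after their values were seen: LOC123904775 (mean 0 CPM in mock and 0.387 at 7 dpi), LOC123904788 (2 reads in mock, and 3.96 CPM at 7 dpi) and the lncRNA gene LOC123904796 (0 and 1.08 CPM). With mock at or near 0 their fitted fold changes depend on the prior count and are not given. Shared regulation or gene duplication might underlie such runs; neither was tested.

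Other splits of the same libraries were compared with the real ones. For all Phoma libraries against mock, 1 of 84 splits, the real one, gave as many as 580 called genes (highest other 151). The real split alone also gave as many as 492 genes changed by at least 2-fold (highest other 151). It likewise had the most genes without overlap, 4182 (highest other 3167). The comparison and this test were both chosen after the data were examined, so chance is made less likely for these counts but is not excluded. The split with 151 calls set Phoma 3 dpi replicate 3 and Phoma 7 dpi replicates 1 and 3 against the rest. The comparisons of 3 with 3 libraries have 10 splits, too few for a share below 0.05. At 7 dpi 1 split gave as many as 630 called genes (highest other 0), 1 as many as 611 changed at least 2-fold (highest other 0), 1 as many as 5016 DESeq2 calls (highest other 680), and 5 as many as 3 gene groups (highest other 8). At 3 dpi 1 split gave as many as 3 called genes (highest other 0), all of them changed at least 2-fold, and 6 as many as 2 gene groups (highest other 9). Between the time points the real counts of called genes and of those changed at least 2-fold were 0, reached by 10 of 10 splits (highest other 5), and 9 gave as many as 1 gene group (highest other 9). Some splits called several times the real number of gene groups. A structure of the samples that does not follow the groups would give this. So would a preset correlation (0.01) below the estimated one, which was 0.446 for nuclear rRNA genes but 0.0114 for lncRNA genes at 7 dpi. Neither was tested.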
